A study of Mus musculus with 6 samples.

How the data were processed

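RNA of 6 samples of SVI mouse podocytes, grown at 38 °C in medium with 10% serum, was measured on Affymetrix mouse expression arrays, 3 from unstretched and 3 from stretched cells. Groups and replicate numbers were taken from the sample titles. The deposited values are log2 expression values, 1 per probe set and array, and per the submitters' processing notes they were made with RMA, a method that by default corrects background, quantile normalizes probes and summarises them per probe set. The version of RMA and the genome build are not given in the sources used here, and scanner files and detection calls were not used here, so signal over background is unknown and low values can be background. Of the deposited values, 99.9% were whole multiples of 1/11 of a step of 1/2048 log2 unit (tolerance 0.01 of that multiple), as a mean over 11 probe values would give. Such steps do not by themselves show that the scale is log2 or how RMA was run. The values ran from 2.67 to 13.9, a range that log2 intensities can have. RMA compresses changes of dim probe sets and sets the overall level of arrays equal, so a global rise or fall of RNA cannot be seen.

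The table held 45101 probe sets, of which 64 controls were left out. The platform's annotation listed 35890, 13 of them controls, 34958 with 1 gene symbol and 932 with several, and 9160 probe sets other than controls were not listed and stay unnamed here. Of the probe sets with 1 symbol, 34754 matched a gene ID in the RefSeq table of mouse assembly GRCm38, used for names and gene order, and 0 symbols changed. Each of 18193 genes was tested by the probe set with the highest mean log2 value over all 6 arrays, and 9010 genes had more than 1. No filter on dim probe sets was applied. Among the 147 genes named by the rule stated here, 93 had more than 1 probe set, 52 had another that passed in the same direction and 1 in the opposite direction, and 18 had a mean below that of the median gene.

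Stretched minus unstretched was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without covariates, at a Benjamini-Hochberg adjusted p under 0.05. Values with an SE are log2 changes from this fit, with n = 3 per group. Lists of genes were tested with camera at a preset correlation of 0.01, adjusted over 35 lists, beside an estimated correlation, under which 0 lists passed, and fry, in which 19 passed. Counts of list members were adjusted over all genes and over the list alone. Single values were compared with two-sided exact permutation tests, whose smallest p is 0.1. Lists, design, alternatives and the rule for naming genes were fixed before the data were examined, save for cyclic loess between arrays and tests named as chosen later. The rule names Cd9, the 10 highest and 10 lowest called genes without overlap between groups (predicted transcripts left out), up to 4 members of each list by size of the moderated statistic, and called members of lists with 5 or fewer calls.

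Lists covered podocyte genes, tetraspanins and partners, focal adhesion, actin, MRTF-SRF and YAP-TEAD genes, matrix, TGF-beta, immediate early, inflammatory, prostanoid, interferon, cell cycle, p53, stress, metabolic, lysosome, Wnt, channel, junction and ribosomal genes, and markers of 6 other cell types. Alternatives were the replicate number as a fixed or random block, each array left out in turn, other scalings, a filter on dim genes, other choices of probe set, another prior, a minimum change of 1 log2 unit, and other list tests. The steps were tested on simulated data for this comparison, with 200 of 18193 genes changed. Recovery was 100% for changes of 1 log2 unit and 83.0% for changes of 0.5, and 5.67% of calls were false. Of lists with part of their members shifted by 0.3, 10 of 10 were called, and 0 of 30 unshifted lists were. Noise was drawn independently for each gene, so false list calls that arise when members correlate were not tested. Noise shared by the genes of an array was not simulated either. The changed genes were far fewer than the 2681 called in the data. The rates for genes can therefore differ from those in the real data. In the other splits of the 6 real arrays into 3 and 3, up to 7 lists passed. The results of 1 list, and some probe sets by name, are not reported here.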

Results

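Messenger RNA levels were measured in SVI cells, a conditionally immortalized mouse podocyte line. Podocytes are the epithelial cells that wrap the glomerular capillaries of the kidney and form the outer part of its filter. Differentiated cells were either left at rest or exposed to cyclic biaxial stretch at 0.5 Hz with a maximum linear strain of 5% for 3 days. Each of the 2 groups had 3 arrays, and their number limits the precision of each value. The series names 3 independent batches without saying of what, so the p-values measure the spread between these arrays, which may be partly technical. The mean log2 value was 5.70 on every array, and the medians lay between 4.92 and 4.98. The spread was wider on stretched arrays, with an SD over probe sets of 2.08 to 2.10 against 2.03 to 2.06 on unstretched arrays. Across probe sets, Pearson correlations were 0.995 to 0.997 among stretched arrays, 0.993 to 0.994 among unstretched arrays and 0.987 to 0.990 between groups. As a sign of RNA quality, the 3' minus 5' log2 difference of the beta-actin control probe sets was 1.57 ± 0.03 (SD, n = 3) in unstretched and 1.30 ± 0.05 (SD, n = 3) in stretched cells (two-sided exact permutation p = 0.1, the smallest this design allows). For the Gapdh controls it was 0.25 ± 0.07 and 0.16 ± 0.10 (SD, n = 3 each; exact permutation p = 0.4).

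The series title asks about Cd9, a tetraspanin of the cell surface. Cd9, read by a single probe set, rose from a log2 value of 10.00 ± 0.18 in unstretched to 10.70 ± 0.09 in stretched cells (SD, n = 3 each). The log2 change was 0.70 (SE 0.10, 95% interval 0.47 to 0.93, limma adjusted p = 0.00154), a level 1.62-fold higher. All 3 stretched values lay above all 3 unstretched values, and the exact permutation test gave p = 0.1, the smallest it can give here. Of the 29 tetraspanins measured, 2 rose and 3 fell past the threshold. Tspan31 rose by 0.33 (SE 0.09), while Tspan9 fell by 0.57 (SE 0.08), Tspan5 fell by 0.42 (SE 0.08) and Tspan18 fell by 0.32 (SE 0.09), all on the log2 scale. Adjusted over the list alone, the counts were also 2 and 3, and the family as a group did not pass (camera adjusted p = 0.972). The Tspan5 and Tspan18 calls ended when all probe sets of a gene were averaged (adjusted p = 0.250 and 0.398), and that of Tspan18 also without stretched replicate 1 (0.129), 2 (0.0636) or 3 (0.0715) or unstretched replicate 2 (0.0949) or 3 (0.0594). The Tspan31 call ended without stretched replicate 1 (adjusted p = 0.122), 2 (0.0593) or 3 (0.122) or unstretched replicate 1 (0.0850) or 2 (0.120). It also ended with quantile normalization again (0.0875) or cyclic loess (0.0825). With every probe set tested, the Tspan31 probe set used here did not pass (0.0530), but another, dimmer one rose by 0.45 and passed (limma adjusted p = 0.00674).

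**Figure D1:**
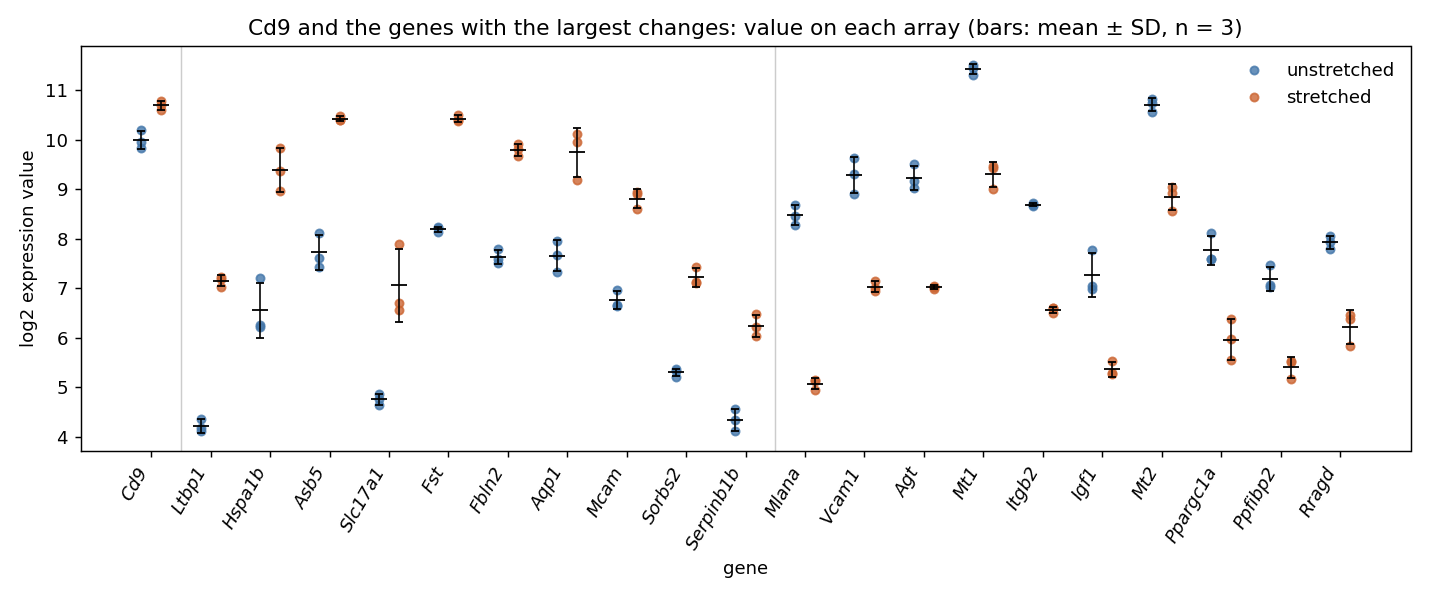
Log2 expression value (vertical axis) of Cd9, of the 10 genes with the highest and of the 10 with the lowest log2 change (horizontal axis), on each of the 3 unstretched and 3 stretched arrays. Points are arrays and bars are mean ± SD; for each gene shown the 2 groups do not overlap.

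Proteins that bind tetraspanins, and growth factors shed near them, moved in both directions. Of 17 measured, 3 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.164). The integrin subunit Itga3 rose by 0.72 (SE 0.09), the hyaluronan receptor Cd44 rose by 0.48 (SE 0.09), and Igsf8, a direct partner of Cd9, rose by 0.50 (SE 0.12). The laminin-binding subunit Itga6 fell by 1.19 (SE 0.15) and the growth factor Tgfa fell by 0.29 (SE 0.08) on the log2 scale. The Igsf8 call ended without stretched replicate 3 (adjusted p = 0.0745) and without unstretched replicates 1 (0.0587) and 2 (0.0634). Another probe set of Tgfa passed in the opposite direction, the call ended whichever single array was left out (adjusted p = 0.0512 to 0.137) and under other scalings (0.0566 to 0.0650), and its log2 change was 0.14 with all probe sets averaged.

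Stretch changed the levels of 2681 of 18193 genes (limma, Benjamini-Hochberg adjusted p under 0.05), of which 1452 rose and 1229 fell. Among genes named by the fixed rule, the largest rises were in Ltbp1, which binds latent TGF-beta in the matrix (log2 change 2.94, SE 0.10, adjusted p = 1.09e-07), the inducible heat shock protein gene Hspa1b (2.83, SE 0.26, adjusted p = 9.79e-05) and Asb5 (6.51-fold higher, SE of the log2 change 0.15, adjusted p = 4.90e-06). The phosphate transporter gene Slc17a1 rose by 2.30 (SE 0.27), the activin antagonist Fst by 2.23 (SE 0.08), the matrix glycoprotein gene Fbln2 by 2.17 (SE 0.10) and the water channel gene Aqp1 by 2.09 (SE 0.22). Mcam, an adhesion molecule, rose by 2.05 (SE 0.12), the stress fibre adaptor Sorbs2 by 1.92 (SE 0.11) and Serpinb1b by 1.91 (SE 0.13). The probe set of Hspa1b carries a suffix for probes shared between transcripts, but another without such a suffix had a log2 change of 2.81 (adjusted p = 1.97e-04 over all probe sets). The single probe set of its near-identical copy Hspa1a had a log2 change of 0.27 (adjusted p = 0.0995), and signal of the pair may not be fully separated. Serpinb1b also has close paralogs.

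The largest fall among them was in Mlana, a melanosome protein gene, which was 10.6-fold lower in stretched cells (log2 change -3.40, SE 0.11, adjusted p = 1.09e-07). The leukocyte adhesion molecule Vcam1 fell by 2.25 (SE 0.16), angiotensinogen (Agt) fell by 2.21 (SE 0.12) and the integrin subunit Itgb2 fell by 2.12 (SE 0.08). The metallothioneins Mt1 and Mt2, similar in sequence, fell by 2.12 (SE 0.12) and fell by 1.86 (SE 0.13). The growth factor Igf1 fell by 1.90 (SE 0.18), Ppargc1a, a coactivator of mitochondrial genes, fell by 1.80 (SE 0.20), Ppfibp2 fell by 1.78 (SE 0.14) and Rragd, a GTPase of lysosomal nutrient sensing, fell by 1.71 (SE 0.15). Changes were mostly small, with a median absolute log2 change of 0.47 among the called genes and a size of at least 1 in 78 that rose and 81 that fell. The groups did not overlap in 5925 genes (32.6%, against 10% by chance) and in 2666 of the called genes. Rises made up 54.2% of calls as deposited, 42.6% (1147 higher, 1546 lower) once the arrays were quantile normalized again and 62.0% (1669 higher, 1025 lower) with arrays centred on their medians. Without stretched replicate 1 the calls numbered 1661 (872 higher, 789 lower), without stretched replicate 3 they numbered 1750 (767 lower), and without stretched replicate 2 the lower calls numbered 780.

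**Figure D2:**
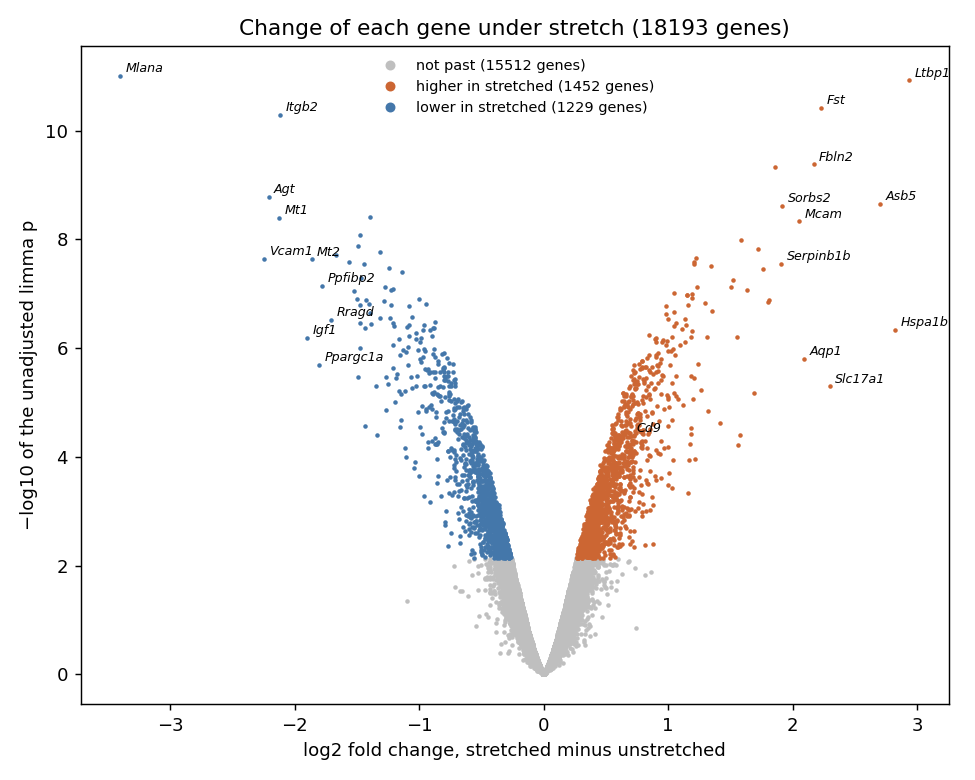
Log2 fold change of stretched minus unstretched cells (horizontal axis) against −log10 of the unadjusted limma p (vertical axis) for 18193 genes. Orange points are the 1452 genes that rose, blue points the 1229 that fell, grey points those not past the threshold, and Cd9 and the genes with the largest changes are named.

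Genes of the actin cytoskeleton rose as a group. Of 41 measured, 20 rose, 0 fell and 21 did not pass; adjusted over the list alone 25 rose and 0 fell, with limma throughout. The median log2 change was 0.29 (camera adjusted p = 3.77e-12, adjusted p = 0.175 with an estimated correlation). The LIM protein gene Pdlim2 rose by 1.20 (SE 0.08), calponin 1 (Cnn1) by 0.85 (SE 0.09), filamin A (Flna) by 0.77 (SE 0.09) and transgelin (Tagln) by 0.73 (SE 0.08). The targets of SRF and its actin-sensing MRTF coactivators share 12 genes with that list. Of 30 measured, 13 rose and 1 fell, and 18 rose and 1 fell adjusted over the list alone (median 0.32, camera adjusted p = 2.29e-08, adjusted p = 0.228 with an estimated correlation). Filip1l rose by 1.86 (SE 0.09), and the gene that fell was Egr1, an immediate early transcription factor (log2 change -1.47, SE 0.13). The beta-actin control, whose 3' minus 5' difference changed by -0.27 between the groups, reads a transcript of the actin list.

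Integrin and focal adhesion genes shifted upward too. In the focal adhesion list 13 of 37 rose and 2 fell, and 14 and 2 adjusted over the list alone (median 0.16, camera adjusted p = 0.00139, adjusted p = 0.175 with an estimated correlation). Fblim1, which links filamin to adhesion sites, rose by 1.23 (SE 0.10) and the actin regulator Vasp by 0.79 (SE 0.12). Targets of YAP and TEAD did not pass as a group (6 of 29 rose, 2 fell, 11 and 3 adjusted over the list alone, camera adjusted p = 0.129). Among them tissue factor (F3) rose by 0.94 (SE 0.14), Dlc1 rose by 0.94 (SE 0.17) and Fjx1 fell by 0.74 (SE 0.09).

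Matrix genes leaned upward. Of 46 structural genes, 11 rose and 2 fell, and 11 and 3 adjusted over the list alone (median 0.08, camera adjusted p = 0.0278, adjusted p = 0.310 with an estimated correlation). Fibronectin (Fn1) rose by 1.22 (SE 0.08) and tenascin C (Tnc) by 0.68 (SE 0.09), while the proteoglycan decorin (Dcn) fell and was 2.83-fold lower (SE of the log2 change 0.12). In the TGF-beta and BMP list 9 of 32 rose and 1 fell, with the same counts adjusted over the list alone (median 0.05, camera adjusted p = 0.0489, adjusted p = 0.239 with an estimated correlation). Besides Ltbp1 and Fst, the activin subunit Inhba rose by 0.67 (SE 0.11) and the feedback inhibitor Pmepa1 rose by 1.00 (SE 0.16). Enzymes that remodel matrix did not pass as a group (10 of 34 rose, 4 fell, 11 and 5 adjusted over the list alone, camera adjusted p = 0.0819). The crosslinking enzyme Lox rose by 1.14 (SE 0.10), Adamts5 by 0.95 (SE 0.11) and Mmp10 by 0.77 (SE 0.11). The structural list lost its call without unstretched replicate 2 (adjusted p = 0.0734) or stretched replicate 3 (0.0919), without dim genes (0.0829), with averaged probe sets (0.114) and with every probe set tested (0.133). The TGF-beta list lost its call without unstretched replicate 2 (0.0947) or 3 (0.108) or stretched replicate 3 (0.103), with arrays centred on their medians (0.0563) or quantile normalized again (0.107), with cyclic loess (0.109) and without dim genes (0.162).

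**Figure D3:**
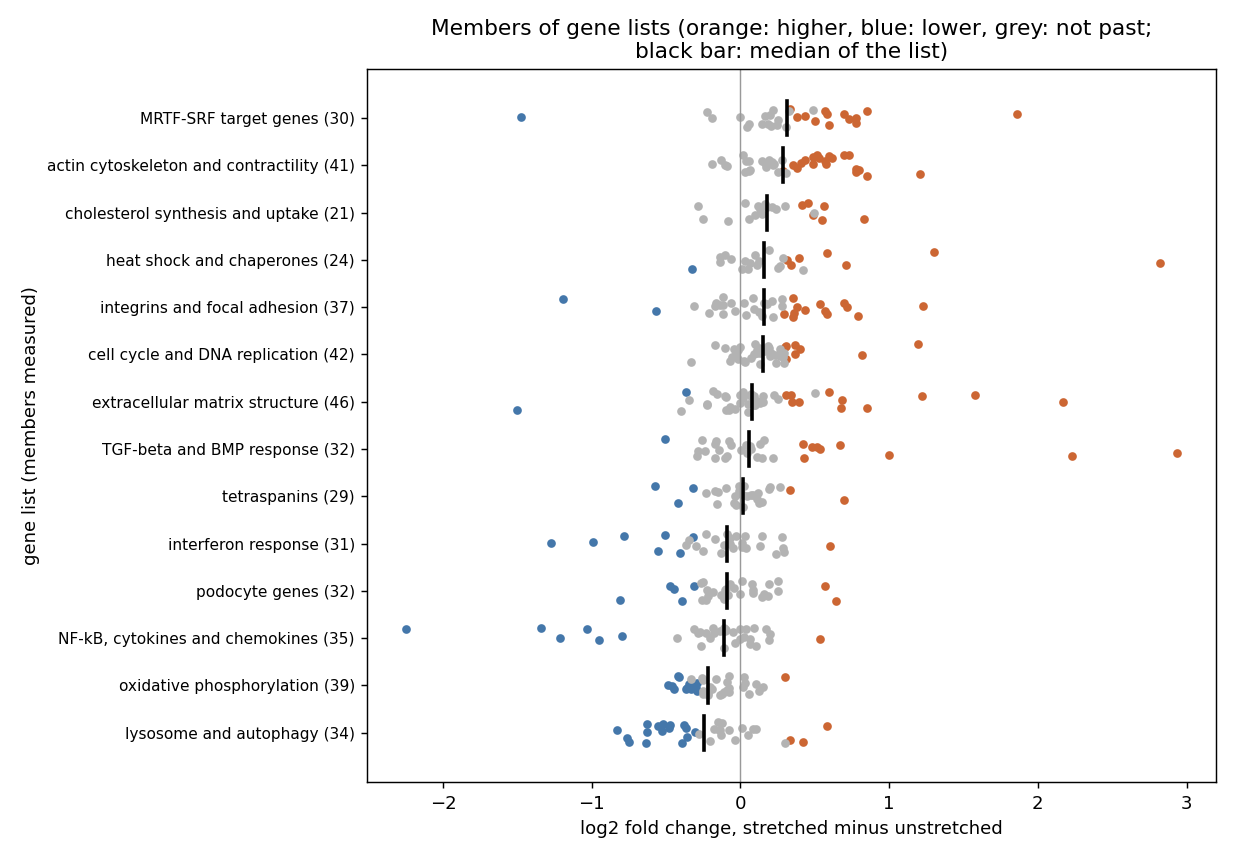
Log2 fold change of stretched minus unstretched cells (horizontal axis) for the measured members of the 12 described gene lists past the camera threshold and of the podocyte and tetraspanin lists (vertical axis, number measured in brackets). Points are genes, orange where they rose, blue where they fell and grey where they did not pass, and black bars are list medians, from 0.32 for MRTF-SRF targets to -0.24 for lysosome and autophagy genes.

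Cell cycle, chaperone and cholesterol genes shifted upward. Of 42 cell cycle genes 9 rose and 0 fell in limma, and 13 and 0 adjusted over the list alone (median 0.15, camera adjusted p = 1.76e-04, adjusted p = 0.234 with an estimated correlation). The replication licensing factor Cdc6 rose by 1.20 (SE 0.11). Of 24 heat shock and chaperone genes 7 rose and 1 fell, and 10 and 1 adjusted over the list alone (median 0.16, camera adjusted p = 0.00108, adjusted p = 0.234 with an estimated correlation). Besides Hspa1b, the small heat shock protein gene Hspb1 rose by 1.30 (SE 0.11), Hsph1 by 0.71 (SE 0.12) and the cochaperone gene Bag3 by 0.58 (SE 0.12). Of 21 genes of cholesterol synthesis and uptake 6 rose and 0 fell in limma, and 7 and 1 adjusted over the list alone (median 0.18, camera adjusted p = 0.00225, adjusted p = 0.403 with an estimated correlation). Squalene synthase (Fdft1) rose by 0.83 (SE 0.14) and the sterol carrier gene Stard4 by 0.45 (SE 0.10). The Fdft1 probe set carries the suffix for probes shared between transcripts. Another without it had a log2 change of 0.50 and did not pass (limma adjusted p = 0.0663 over all probe sets). The cholesterol list lost its call without unstretched replicate 3 (adjusted p = 0.0533) and in fry (0.189). With quantile normalization again, which levels the spread of the arrays, the camera adjusted p rose to 0.0276 for cell cycle and cholesterol and 0.0183 for heat shock.

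Lysosomal and mitochondrial genes shifted downward. Of 34 lysosome and autophagy genes 16 fell and 3 rose, and 17 and 4 adjusted over the list alone (median -0.24, camera adjusted p = 1.66e-05, adjusted p = 0.255 with an estimated correlation). The hydrolase subunit Hexa fell by 0.83 (SE 0.09), the lysosomal calcium channel gene Mcoln1 fell by 0.76 (SE 0.09), the membrane protein gene Scarb2 fell by 0.75 (SE 0.09) and the proton pump subunit Atp6v1a fell by 0.64 (SE 0.09). Of 39 oxidative phosphorylation genes 13 fell and 1 rose, and 19 and 1 adjusted over the list alone (median -0.22, camera adjusted p = 2.09e-05, adjusted p = 0.234 with an estimated correlation). The complex I subunit Ndufs7 fell by 0.49 (SE 0.09) and the ATP synthase subunit Atp5c1 fell by 0.45 (SE 0.08).

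Inflammatory and interferon-response genes shifted downward as well. Of 35 NF-kB, cytokine and chemokine genes 6 fell and 1 rose, with the same counts adjusted over the list alone (median -0.11, camera adjusted p = 0.00733, adjusted p = 0.292 with an estimated correlation). Besides Vcam1, the iron-chelator carrier Lcn2 fell by 1.21 (SE 0.11), the chemokine gene Cxcl10 fell by 0.95 (SE 0.10) and the NF-kB subunit Relb fell by 0.80 (SE 0.09). Of 31 interferon-response genes 7 fell and 1 rose, and 9 and 4 adjusted over the list alone (median -0.09, camera adjusted p = 0.0415, adjusted p = 0.234 with an estimated correlation). The immunoproteasome subunit Psmb9 fell by 1.27 (SE 0.10), the peptide transporter Tap1 fell by 0.99 (SE 0.10), Gbp2 fell by 0.78 (SE 0.11) and Ifit2 fell by 0.55 (SE 0.08). The interferon list lost its call without unstretched replicate 3 (adjusted p = 0.0829) or stretched replicate 2 (0.0708), with quantile normalization again (0.0516) and with cyclic loess (0.0514).

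Podocyte genes did not pass as a group: of 32 measured, 2 rose and 5 fell, the same as adjusted over the list alone (median -0.09, camera adjusted p = 0.368). The chloride channel protein gene Clic5 fell by 0.81 (SE 0.09) and the actin-associated synaptopodin gene Synpo fell by 0.45 (SE 0.08), while the intermediate filament gene Nes rose by 0.57 (SE 0.09) and the Rac regulator Arhgap24 rose by 0.64 (SE 0.12). The calls of Synpo and Nes ended with averaged probe sets (adjusted p = 0.0837 and 0.131). Of 34 adhesion and junction genes 7 rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.386). N-cadherin (Cdh2) rose by 1.21 (SE 0.09) and Cdh11 by 0.98 (SE 0.09), while claudin 2 (Cldn2) fell by 1.01 (SE 0.08) and keratin 7 (Krt7) fell by 0.95 (SE 0.10).

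Other lists held large single changes in both directions. Of 31 immediate early and AP-1 genes 9 rose and 7 fell (12 and 8 adjusted over the list alone, camera adjusted p = 0.164): Fosl2 rose by 0.96 (SE 0.09) and Ier5 by 0.79 (SE 0.08), while Egr2 fell by 1.10 (SE 0.10). Of 29 oxidative stress genes 10 rose and 5 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.164), with a median of 0.20 but a mean of -0.03: heme oxygenase (Hmox1) rose by 1.15 (SE 0.09) and Gsta3 fell by 1.08 (SE 0.09). In the unfolded protein response list 4 of 30 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.164): the chaperone gene Hspa5 rose by 0.50 (SE 0.11) and Manf by 0.52 (SE 0.09), while the pro-apoptotic factor Ddit3 fell by 1.46 (SE 0.11). Of 33 lipid genes 5 rose and 5 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.824, median -0.01 and mean 0.02): Angptl4, an inhibitor of lipoprotein lipase, rose by 1.59 (SE 0.10) and the lipid droplet gene Plin4 fell by 0.97 (SE 0.10). Of 32 glycolysis and hypoxia genes 2 rose and 6 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.576), and Ndrg1 fell by 0.69 (SE 0.09). Of 29 p53 targets and cell cycle inhibitors 5 rose and 4 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.942, median -0.04 and mean 0.01): Cdkn1b rose by 0.80 (SE 0.12) and Zmat3 fell by 0.54 (SE 0.08).

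The remaining pathway lists did not pass either. Of 35 Wnt genes 2 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.452): Ccn5 rose by 0.98 (SE 0.10) and Wnt5a fell by 0.91 (SE 0.10). In the prostanoid and angiotensin list 1 of 24 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.824): these were the prostaglandin receptor Ptger4, which rose by 0.83 (SE 0.16), and Agt. Of 29 mechanosensing and calcium channel genes 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.890). The calcineurin regulator Rcan1 rose by 0.90 (SE 0.09) and the purinergic channel gene P2rx4 fell by 1.14 (SE 0.08), whereas Piezo1 had a log2 change of -0.27 (adjusted p = 0.0569). In the list of 27 ribosomal protein genes 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.508).

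None of the 6 lists of other cell types passed in camera. Of 15 endothelial markers 0 passed in limma, also adjusted over the list alone (camera adjusted p = 0.510), and 3 had an unadjusted p under 0.05 (Plvap and Cldn5 lower, Ehd3 higher in stretched cells). Of 14 mesangial and smooth muscle markers 3 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.345): Tbx18 rose by 1.03 (SE 0.10) and Ptn fell by 0.86 (SE 0.12), a call that ended with averaged probe sets (adjusted p = 0.0593). Of 15 fibroblast markers 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.974, median 0.08 and mean below 0): S100a4 rose by 1.76 (SE 0.13), while Dcn and Twist2 (-0.76, SE 0.09) fell. Of 12 parietal epithelial markers 3 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.988): Cd24a rose by 0.71 (SE 0.09) and Cp fell by 0.71 (SE 0.10). The other Cp probe sets had log2 changes from -0.77 to -0.01. The next brightest had -0.32 and did not pass (limma adjusted p = 0.0532 over all probe sets). Of 13 tubule markers 2 rose and 0 fell in limma, also adjusted over the list alone (camera adjusted p = 0.156): these were Aqp1 and Cubn, which rose by 0.49 (SE 0.12) and whose call ended without stretched replicates 1 (adjusted p = 0.0776) and 2 (0.0716) and unstretched replicate 2 (0.0562). Of 16 macrophage and leukocyte markers 1 rose and 3 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.128): Cd14 rose by 0.81 (SE 0.10), Cd68 fell by 0.89 (SE 0.12), Csf1r fell by 0.50 (SE 0.11) and Fcer1g fell by 0.49 (SE 0.11), and the Fcer1g call ended without stretched replicate 1 (adjusted p = 0.0663) or unstretched replicate 2 (0.0564).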

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

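The test of the spike-in controls was chosen after their values were seen. Of 10092 probe sets without a single gene symbol, which no comparison of genes uses, 220 were higher in stretched than in unstretched cells at the same threshold and 406 were lower, and 23 and 14 of these changed by at least 1 log2 unit. The hybridization controls, bacterial and phage transcripts added to each sample, drew attention because all 18 of their probe sets were higher on the stretched arrays, with differences from 0.02 to 0.37 and a median of 0.23 log2. These probe sets read only bioB, bioC, bioD and cre, each by several sets, so they are not independent of one another. Their mean per array was 10.20 ± 0.09 in unstretched and 10.41 ± 0.19 in stretched samples (SD, n = 3 each; two-sided exact permutation p = 0.3), and 1 of the 18 passed in limma. Among genes, the median log2 change went from -0.05 in the dimmest to 0.04 in the brightest of 5 equal groups by mean level.

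The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split alone (1 of 10) reached each of its counts: 2681 genes changed, 1452 higher, 1229 lower, 5057 at an unadjusted p under 0.05 and 13 lists. The highest counts in the other splits, with limma and camera, were 0, 0, 0, 1008 and 7.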

How the results depend on the processing

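Cyclic loess was chosen after seeing the data. Cd9 passed under all 15 alternatives run, with log2 changes from 0.62 to 0.80 and adjusted p from 4.99e-05 to 0.00991. Cd9 is bright and has a single probe set. Its log2 change therefore could not move with the replicate blocks, the other prior, the dim filter or other choices of probe set. Of 2172 values of other named genes 2067 kept their side of the threshold, and their direction too where the gene passed. Of the rest 87 no longer passed, 17 newly passed and 1 reversed. Among these named genes 105 of 134 called ones passed under every alternative run. Most were named for the size of their change in these data, so this share does not describe all calls. Of all 2681 calls, 1615 to 2681 were kept, with 1615 without stretched replicate 1 and 1974 with averaged probe sets. Of 329 values of lists that had not passed, 309 stayed so and 20 newly passed, upward for matrix remodelling, YAP-TEAD, immediate early, tetraspanin partner, mesangial, tubule, oxidative stress and unfolded protein lists and downward for ribosomal and macrophage lists. The cause of the changes was not tested, except that leaving out arrays lowers the number of samples.

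The labels do not say that a replicate number marks a shared batch, and the arrays did not settle it: deviations of same-numbered arrays correlated at 0.02, 0.15 and 0.28, with 2 of 3 over 0.1, and 4 of 6 arrays correlated best with their own number. With the number as a replicate block 3102 genes passed, 2627 of them among the 2681, and the TGF-beta list did not (adjusted p = 0.0705); no other list call changed. With the number as a random effect (consensus correlation 0.15) 3283 genes passed. Without each array in turn, genes changed numbered 1661 to 2639, higher 872 to 1450 and lower 767 to 1189. A minimum change of 1 log2 unit left 159.

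Some lists no longer passed. The TGF-beta list had an adjusted p of 0.0563 with arrays centred on medians, 0.107 with quantile normalization again, 0.109 with cyclic loess and 0.162 without dim genes. The interferon list had 0.0516 with quantile normalization and 0.0514 with cyclic loess. The matrix structure list had 0.0829 without dim genes, 0.114 with averaged probe sets and 0.133 with every probe set tested. Cholesterol had 0.189 in fry. With averaged probe sets the log2 change of Tgfa reversed to 0.14. Leaving out each array in turn gave adjusted p ranges of matrix structure 0.00921 to 0.0919, TGF-beta 0.0143 to 0.108, interferon 0.0265 to 0.0829, cholesterol 0.000234 to 0.0533. With an estimated correlation 0 lists passed, the adjusted p being for focal adhesion and actin 0.175, MRTF-SRF 0.228, matrix structure 0.310, TGF-beta 0.239, NF-kB 0.292, interferon, cell cycle, heat shock and oxidative phosphorylation 0.234, cholesterol 0.403, lysosome 0.255. The random effect and the other prior were not run for lists. Without detection calls, signal over background cannot be given, so calls of dim genes are the least certain.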

Other observations

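The tests of macrophage transcripts and of placement by brightness were chosen after the results were seen. A second test of the same macrophage transcripts, of their level in unstretched cells (8 of 8 below the median gene), was also tried. It was not used as a test of its own, since levels of different probe sets cannot be compared so. The low level of these transcripts serves below only as the reason why the test of their changes decides nothing. For the bound on RNA quality, set before its value was seen, the judgement that it was too wide came afterwards.

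Lysosome and autophagy genes were lower in stretched cells (median -0.24), and Mlana and Rragd, known targets of the MiT/TFE transcription factors that control lysosome genes, were among the largest falls. In a further list of 44 MiT/TFE targets written before its values were seen, 41 were measured, 0 rose and 16 fell in limma, with a median of -0.28 (camera p = 1.76e-08, p = 0.0599 with an estimated correlation); as examples chosen after their values were seen, Gpnmb fell by 1.03 (SE 0.12) and Flcn fell by 0.57 (SE 0.13), while the pigment genes Pmel, Dct and Tyr did not pass (0.25, -0.20 and 0.02). A shift of all genes of that brightness is argued against, since 0% of 10000 random lists matched on mean level had a median as low as the lysosome list (central range -0.05 to 0.15). RNA degradation that differs between groups stays open. The mean 3' minus 5' difference of Gapdh and beta-actin was lower in stretched cells by 0.178 (change -0.178), under the bound of 0.5 set in advance. It separated every array by group (exact permutation p = 0.1, the smallest possible), so that bound was too wide. The separation came from beta-actin (-0.27), while the Gapdh values overlapped between groups (-0.09, exact permutation p = 0.4). Both beta-actin ends rose in stretched cells, the 3' set by 0.35 and the 5' set by 0.62. Changes of the 3' and 5' sets were 0.21 and 0.13 for 18S RNA and 0.30 and 0.41 for the transferrin receptor. For pyruvate carboxylase they were -0.03 and 0.01. The direction in which a difference in degradation would move lysosome genes was not tested. Lower MiT/TFE activity may underlie the pattern and remains a hypothesis beside RNA degradation, since the further targets are mostly lysosomal genes too and any other cause that lowers such genes would lower them.

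Single genes known from leukocytes were lower in stretched cells, with Itgb2 (-2.12), Irf8 (-1.23; chosen after its value was seen), Cd68 (-0.89) and Csf1r (-0.50), though Cd14 rose by 0.81 and the macrophage and leukocyte list as a whole did not pass (camera adjusted p = 0.128, adjusted p = 0.310 with an estimated correlation). Fewer macrophages in the stretched dishes would lower their abundant transcripts alike. Of 8 such transcripts (Lyz2, Tyrobp, C1qa, C1qb, Laptm5, Ptprc, Aif1 and Adgre1), 8 had a 95% interval above a fall of 1 log2 unit and 3 had one below 0 (C1qb -0.25, Ptprc -0.28 and Adgre1 -0.21), but 0 passed and each was dimmer than the median gene, with little room to fall. This decides nothing, so fewer macrophages and a change in the podocyte line itself both stay open, and the latter was not tested.

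Neighbouring genes tended to change in the same direction. Of 452 pairs of called genes next to each other among those measured, 61.9% changed the same way, against a central range of 45.5% to 55.3% in 10000 random placements (permutation p = 2.00e-04), such as Psmb9 and Tap1 (-1.27 and -0.99). Paralogs that share probes or ancestry are argued against as the whole cause, since without pairs of the same symbol stem the share was 61.0% of 426 pairs (45.2% to 55.5% at random). A shift by brightness shared by neighbours is argued against too, as placements among genes of like mean level had a central range of up to 55.3%. Shared regulation of neighbours may contribute, but GC content and overlapping transcripts were not tested and stay open.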
